A study of Rattus norvegicus with 2 samples.

How the data were processed

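RNA came from spinal cord of rats 21 days after surgery, from a BCP group and a sham group of 3 animals each, per the labels' protocols. Per the same protocols, ribosomal RNA was removed, linear RNA was digested with 16 units of RNase R for 15 min, and strand-marked libraries were made from randomly primed cDNA. There was 1 sample and 1 column of each kind per group. The source label of both samples names the injected cell line, while the tissue label names spinal cord, and the tissue label was followed.

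The authors deposited a table of circRNAs with back-splice junction read counts and a depth-scaled value for each library. The counts are whole numbers, and each is 0 or at least 2. The deposited columns headed TPM are CPM values: for every count above 0 in sham (9003) and in BCP (7375) they equal the count scaled to the column total, to within 0.001 CPM, and 0 is written as 0.001. CASAVA 1.8, BWA and the rn6 build are named, per the submitters' processing notes. The BWA version, the circRNA caller, its read minimum and its annotation are not given in the sources used here. RNase R digestion and the caller set which molecules are counted, so the values describe circRNA reads and not the linear RNA of the host genes. A read minimum per circRNA makes thinly covered circRNAs drop to 0, more so in the shallower library.

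Positions are those of the table. Its gene field also holds small RNA family names and names that recur across a chromosome. Family names of small nucleolar, Cajal body and spliceosomal RNAs and Y RNA were dropped, and so were 65 names whose circRNAs covered over 3 Mb of a chromosome. These rules for names were set after the file was seen. A circRNA with a single name left was given that host (10004), 1563 had none left and 32 had several. Of 3865 host names, 3745 matched a symbol or synonym in the RefSeq gene table of the GRCr8 assembly, which was used for names alone. Exons, introns and untranslated regions were not used here. No circRNA lay on chromosome Y, and 1 lay on an unplaced scaffold.

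Counts were scaled to the total of circRNA reads of each library, 113033 in sham and 78836 in BCP. The log2 ratio is of BCP over sham with a pseudocount of 0.5 reads. A circRNA or host gene was tested with at least 10 reads over both libraries, which kept 3502 circRNAs with 82.9% of the reads, and met the size rule with a ratio of at least 2-fold and a 95% conditional exact binomial (Clopper-Pearson) interval that excluded 1. Single shares have exact binomial (Clopper-Pearson) intervals. The rule compares the reads of these libraries, not the conditions, and no p-value across replicates could be had with 1 library per group. No fold is given against a library where a circRNA is listed at 0. The chance level of the rule came from 100 redraws of the reads of each circRNA at equal levels, with counts under 2 set to 0.

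The 16 host gene lists were fixed before the data were examined: MAPK and growth factor signalling, excitatory synapse, inhibitory synapse, presynaptic release machinery, ion channels, oligodendrocyte, astrocyte, microglia and macrophage, vessel, pericyte and meninges, extracellular matrix, blood and lymphoid, skeletal muscle, ganglion neuron and Schwann cell, proliferation, conserved circRNA hosts, and RNA-binding proteins of splicing and circularization. The median log2 ratio of a list with at least 5 tested circRNAs was placed among 10000 random lists of the same size matched on reads. The size rule, the design and the rule for named circRNAs were fixed before the data were examined as well. That rule took the 10 most abundant circRNAs, the 12 largest ratios per direction among those that met the size rule, the circRNAs of Col8a1, up to 2 per list and direction, and the 5 host genes with most circRNAs. Further circRNAs with reads in both libraries and host gene sums were named after their values were seen. Some items that the rule takes in are not reported here.

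The steps were tested on simulated data before use. In 20 simulated pairs of libraries with 200 changed circRNAs each among 3502, the size rule called 29.9% of those changed 2-fold, 65.5% of those changed 3-fold and 86.5% of those changed 5-fold, and 2.51% of unchanged ones. For the lists, 97.0% of unshifted simulated lists lay in the middle 95%. An intraclass correlation of 0.5 was recovered as 0.483. A scan of 5 Mb windows with 10000 permutations recovered the 1 simulated window that was lowered and called 0 others. That window was chosen for holding at least 10 circRNAs, after a first trial with fewer permutations and another window recovered 0.

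Alternatives fixed beforehand were median-of-ratios (DESeq2 1.42.0) and TMM (edgeR 4.0.16) scaling of the counts the authors deposited, other read minimums, ratios and pseudocounts, thinning of the deeper library, host gene sums in place of circRNAs and shares of circRNAs in place of reads. Restriction to circRNAs with reads in both libraries, to circRNAs with 1 host name, and 1 read in place of each 0 were chosen after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3.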

Results

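Circular RNAs (circRNAs), closed molecules made when a downstream splice site is joined back to an upstream one, were profiled in the spinal cord of rats with bone cancer pain (BCP) and of sham-operated rats. Live Walker 256 rat mammary carcinoma cells had been placed in the marrow cavity of the tibia in the BCP group, and boiled cells in the sham group. Tissue was taken 21 days after surgery, and 3 animals are described per group. There was 1 library per group, so no difference has a replicate check, and every comparison is between these 2 libraries and not between the conditions. Whether the RNA of the animals was pooled is not given in the sources used here. The table held 113033 back-splice reads in the sham library and 78836 in the BCP library, over 11599 circRNAs given by chromosome, start and end (build rn6). All intervals are 95%. Except where a bootstrap over circRNAs is named, they cover only the counting error of independent reads. Reads without molecular identifiers are not independent molecules, so these intervals may be too narrow.

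The first question was which circRNAs each library held. The most abundant was hosted by Gigyf2, which encodes a regulator of mRNA translation (chromosome 9, 94463647 to 94481167). It took 6.05% of sham reads (exact binomial interval 5.91 to 6.19) and 6.10% of BCP reads (5.93 to 6.27). A circRNA of Ssbp2, a gene for a single-stranded DNA binding protein (chromosome 2, 20507150 to 20531444), came next with 2842 and 1708 reads in sham and BCP. The others among the 10 most abundant had Zfp609, Elf2, Crebrf, Cdyl, Gtf2i, Tmeff1 and AABR07060133.1 as hosts, and 1 on chromosome 3 (81127393 to 81143240) had no single host name. None of these 10 met the size rule. The widest ratios among them were 1.34-fold lower in BCP for Crebrf (1.19 to 1.51) and 1.28-fold higher for AABR07060133.1 (1.12 to 1.46). The 10 most abundant circRNAs of each library held 13.2% of sham reads (13.05 to 13.4) and 13.03% of BCP reads (12.8 to 13.3).

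The sham library listed 9003 circRNAs and the BCP library 7375. Sham was 1.43 times as deep, and after thinning to the depth of BCP it held a mean of 7603 circRNAs (range 7516 to 7658 over 100 thinnings). Both libraries listed 4779 circRNAs (41.2% of the table). The 4224 listed in sham alone held 15.9% of its reads, and the 2596 listed in BCP alone held 12.4%. The median count was 4 reads in each library. The smallest count above 0 was 2, so a circRNA listed at 0 is not shown to be absent. Host gene names came from the table: 10004 circRNAs had 1 host, and 3865 genes hosted at least 1 circRNA. The genes with most circRNAs were Rims2 (48), Nupr1 (24), Stk39 (24), Atrnl1 (21) and Ttll5 (21). The circRNAs given to Nupr1 spread over 1011523 bp, so that assignment is doubtful. CircRNAs without a single host took 13.7% of sham reads (13.5 to 13.9) and 13.2% of BCP reads (12.96 to 13.4). Chromosome X gave 1.24% (1.17 to 1.30) and 1.26% (1.18 to 1.34). The median genomic span was 9988 bp among circRNAs listed in sham and 8855 bp in BCP. Spans of at most 500 bp took 5.25% of sham reads (5.12 to 5.38) and 6.02% of BCP reads (5.86 to 6.19). Strand and circRNA type were not analysed here.

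The main question of the design was which circRNAs differed between BCP and sham. Of 3502 circRNAs with at least 10 reads over both libraries, 274 were higher and 257 lower in BCP by the size rule, a ratio of at least 2-fold with an interval that excluded 1. Ksr2, which encodes a scaffold of the RAF, MEK and ERK kinases, hosted the circRNA with most raw reads, summed over both libraries, among those with reads in both that were higher in BCP (chromosome 12, 44821090 to 44825909). It had 46 reads in sham and 99 in BCP, a ratio of 3.09-fold (2.15 to 4.48). In the other direction, a circRNA of the cadherin gene Cdh7 (chromosome 13, 31140421 to 31163102) had 145 and 40 reads, 2.53-fold lower in BCP (1.77 to 3.68). Many of the circRNAs that met the rule were listed at 0 in the other library: 84 of those higher and 174 of those lower in BCP.

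The 12 circRNAs with the largest ratios in favour of BCP were all listed at 0 in sham, so no fold is given. Brap, whose product is a RAS-responsive ubiquitin ligase that restrains MAPK signalling, led them with 52 reads in BCP (chromosome 12, 40388299 to 40397763). A circRNA without a host on chromosome 6 (141147178 to 141258469) had 50 reads. Hlcs (holocarboxylase synthetase) and RGD1565616 had 48 reads each. The translation initiation factor gene Eif4g3 had 46 reads, and the chromatin regulators Hdac2 and Asxl1 had 43 each. Klhdc1 had 33 reads. Lrrc16a, the chaperone gene Dnajc1, the cystine and glutamate exchanger gene Slc7a11 and the actin regulator gene Evl had 32 each. Among circRNAs with reads in both libraries, 190 were higher in BCP. Of these, picked after their values were seen, Mettl22 went from 5 to 53 reads (15.2-fold, 6.12 to 48.7), Faxdc2 from 4 to 38 (13.6-fold, 4.90 to 52.5) and Map4k1, a kinase gene of blood cells, from 4 to 33 (11.8-fold, 4.21 to 46.0). Others with more reads were Ccdc171 (27 and 84 reads, 4.46-fold, 2.86 to 7.16) and a circRNA without a host on chromosome 20 (5347661 to 5414567; 19 and 119 reads, 8.98-fold, 5.51 to 15.4).

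On the side of sham, the 12 largest ratios were likewise all of circRNAs listed at 0 in BCP. LOC100362999 hosted the first, with 287 reads in sham (chromosome 6, 59301040 to 59301308). Next came a circRNA without a host on chromosome 1 (119464809 to 119545970) with 124 reads. The Rab5 exchange factor gene Rabgef1 had 67 reads, a 150 bp circRNA without a host on chromosome 1 (221152456 to 221152605) had 65, and the centrosomal gene Cep97 had 63. Mboat2, an acyltransferase gene, and Nop58, a gene of the small nucleolar RNA protein complex, had 61 each. A circRNA without a host on chromosome 13 (109457218 to 109588736) had 58. The kinesin gene Kif1b had 57 reads, Mtus2 had 54, the neuronal RNA-binding protein gene Elavl3 had 52 and Rab11fip4 had 50. With reads in both libraries, 83 circRNAs were lower in BCP. Those picked after their values were seen include Rasa2, a gene for a RAS GTPase activator (69 and 19 reads, 2.53-fold lower, 1.51 to 4.46), Cluap1 (44 and 6 reads, 5.11-fold lower, 2.17 to 14.7) and Adgrb3, an adhesion receptor gene of synapses (30 and 4 reads, 5.23-fold lower, 1.84 to 20.4).

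**Figure D1:**
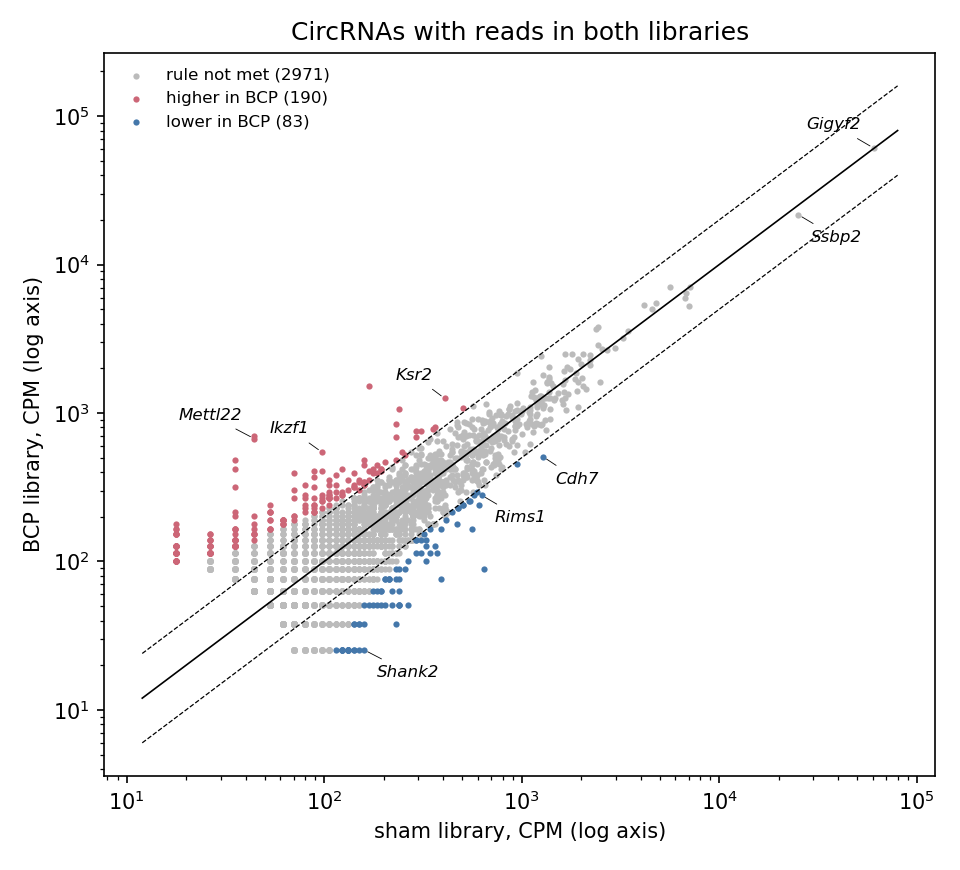
Normalised level (CPM) of each tested circRNA in the sham library (x axis) and the BCP library (y axis), both on log axes, for circRNAs with reads in both libraries. The solid line marks equal levels and the dashed lines a 2-fold ratio; 190 circRNAs lie on the BCP side and 83 on the sham side by the size rule, Gigyf2 and Ssbp2 are the most abundant, and circRNAs listed at 0 in a library are not drawn.

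Redrawing the reads of each circRNA at equal levels 100 times gave a mean of 47.4 higher and 39.0 lower by the same rule, and at most 66 and 53. Among circRNAs with reads in both libraries and at least 100 reads in all (272 circRNAs), the SD of the log2 ratio was 0.49, and counting error alone gives 0.23. Median-of-ratios and TMM scaling moved every log2 ratio by -0.10 and -0.12. Relative to these shifts, 231 circRNAs were higher and 304 lower with median-of-ratios scaling, and 228 and 308 with TMM. Counting error is the only error this rule takes in, and the spread between animals is unknown here.

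No circRNA hosted by Col8a1, a collagen gene that the design text names, was listed. Genes of MAPK and growth factor signalling, the pathway in the series title, hosted 58 tested circRNAs, of which 8 were higher in BCP, 1 was lower and 49 met neither side of the rule. Besides Ksr2, the higher ones included those of the kinase genes Rps6ka5 (14 and 33 reads, 3.38-fold, 1.76 to 6.84), Braf (13 and 23 reads, 2.54-fold, 1.23 to 5.45), Map2k5 (6 and 13 reads) and Stk3 (17 and 27 reads), the RAS inhibitor gene Nf1 (2 and 10 reads) and the receptor gene Igf1r, listed at 0 in sham with 11 reads in BCP. The lower one, of the receptor gene Fgfr2, had 35 reads in sham and was listed at 0 in BCP. Sums over all circRNAs of a gene went both ways. Ksr2 (57 and 106 reads) and Igf1r (3 and 13) met the rule as higher, and Ntrk3 (69 and 23), Sos2 (52 and 15) and Ppp3cb (14 and 2) as lower. The circRNA of Igf1r listed at 0 in sham held 11 of its 13 BCP reads. From circRNAs with reads in both libraries alone, Ntrk3 (62 and 23 reads) and Sos2 (36 and 15) did not meet the rule. Ppp3cb (7 and 2) then had too few reads to be tested. Summed over the list, CPM were 1.09-fold higher in BCP (1.01 to 1.18), but the ratio was 1.02 (0.940 to 1.10) with median-of-ratios scaling and 1.05 (0.963 to 1.14) with 1 circRNA left out, so the interval above 1 rests on the scaling and on a single circRNA. The median log2 ratio was 0.04, at percentile 54.6 of 10000 random lists matched on reads, and it turned to -0.06 with median-of-ratios scaling. The theme of this list comes from the study itself, so it is not independent evidence.

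The summed ratios of the 3 synaptic lists were below 1. Excitatory synapse genes had 32 tested circRNAs, with 0 higher and 4 lower in BCP. The lower ones were hosted by the glutamate receptor gene Grm8 (107 and 36 reads, 2.07-fold lower, 1.41 to 3.11) and the scaffold genes Shank2 (18 and 2 reads, 6.28-fold lower, 1.503 to 55.8), Grip1 (21 reads) and Shank3 (14 reads), the last of these listed at 0 in BCP like Grip1. The summed ratio was 0.888 (0.801 to 0.982), and the median log2 ratio of -0.06 lay at percentile 29.6. Sums over all circRNAs of an excitatory synapse gene went both ways. Grm8 (137 and 42 reads) met the rule as lower, and the glutamate receptor gene Grik4 (11 and 24 reads, 3.13-fold, 1.48 to 7.07) as higher. From circRNAs with reads in both libraries alone, Grik4 (9 and 12 reads) and Grm8 (120 and 42) did not meet it. Presynaptic release genes had 6 higher and 3 lower of 52, with a summed ratio of 0.865 (0.8001 to 0.935) and a median of -0.05 at percentile 30.1. Within this list, the active zone gene Rims1 had a circRNA with 71 and 22 reads (2.25-fold lower, 1.38 to 3.81) and another with 42 reads in sham and listed at 0 in BCP. A pair of Erc1 circRNAs was higher (18 and 27 reads, 2.15-fold, 1.14 to 4.15; 12 and 21 reads, 2.51-fold, 1.18 to 5.59), and the first of them did not meet the rule with median-of-ratios scaling. Inhibitory synapse genes had 0 higher and 1 lower of 10, with a summed ratio of 0.857 (0.692 to 1.06), or 0.797 (0.644 to 0.983) with median-of-ratios scaling, and a median of 0.17 at percentile 65.2, opposite in sign to the mean.

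Ion channel genes had 4 higher and 1 lower of 20. A circRNA each of the calcium channel genes Cacna1a (13 reads), Cacna1b (12 reads) and Cacna1c (11 reads) was listed at 0 in sham. A circRNA of the sodium leak channel gene Nalcn had 4 and 10 reads (3.58-fold, 1.03 to 15.7), a call lost with median-of-ratios scaling. In the other direction, a circRNA of the calcium release channel gene Ryr2 had 18 reads in sham and was listed at 0 in BCP. All 5 circRNAs of the calcium channel gene Cacna1d together had 23 and 2 reads (8.02-fold lower, 1.98 to 70.2). Only 1 of these 5 had reads in both libraries (5 and 2 reads), too few to be tested. The median log2 ratio of the tested ion channel circRNAs was -0.13 at percentile 27.3, and their mean was 0.53. The summed ratio of the list was 0.928 (0.811 to 1.06), which became 0.863 (0.754 to 0.987) with median-of-ratios scaling. RNA-binding protein genes of splicing and circularization had 1 higher (Rbfox2, 16 and 26 reads, 2.33-fold, 1.204 to 4.65) and 1 lower (Elavl3) of 20, a summed ratio of 1.01 (0.891 to 1.15) and a median of 0.09 at percentile 61.3. With median-of-ratios scaling these were 0.941 and -0.02. The circRNA of Elavl3 that was lower had 52 reads in sham and was listed at 0 in BCP. Another circRNA of Elavl3, the most abundant of the list, had 154 and 99 reads and did not meet the rule. Known conserved circRNA hosts had 5 higher and 3 lower of 74, a summed ratio of 1.00 (0.9755 to 1.03; 0.933, 0.907 to 0.959, with median-of-ratios scaling) and a median of -0.06 at percentile 28.3. Rere and Rims2 each hosted circRNAs on both sides. For Rere, circRNAs with 30 and 28 reads in BCP were listed at 0 in sham, and another with 11 reads in sham was listed at 0 in BCP. For Rims2, a circRNA on chromosome 7 (78433861 to 78520474) had 11 reads in sham and was listed at 0 in BCP, and another (78188914 to 78189124) had 4 and 17 reads (6.09-fold, 1.99 to 24.9). None of the 8 lists with at least 5 tested circRNAs had a median outside the middle 95% of random lists.

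Glial and other cell type markers had few reads. Both tested circRNAs of microglia and macrophage genes were higher in BCP: the lymphoid and myeloid transcription factor gene Ikzf1 had 11 and 43 reads (5.60-fold, 2.84 to 12.1; chromosome 14, 91797457 to 91804795), and Dock8 had 12 reads and was listed at 0 in sham. All circRNAs of this list summed to 27 and 80 reads, 4.25-fold higher in BCP (2.72 to 6.84), and 3.32-fold (1.7996 to 6.38) without Ikzf1. Oligodendrocyte genes had 1 higher and 0 lower of 10, a circRNA of the myelin gene Mbp with 27 reads in BCP and listed at 0 in sham (chromosome 18, 79424843 to 79427288). Their median was 0.48 at percentile 90.7 and their summed ratio 1.22 (0.985 to 1.502). Astrocyte genes had 1 higher (Slc7a11) and 1 lower of 4, with a summed ratio of 0.986 (0.754 to 1.29). Vessel, pericyte and meninges genes had 1 lower of 4 (Flt1, 20 reads in sham and listed at 0 in BCP) and a summed ratio of 1.12 (0.778 to 1.60). Sums over all circRNAs of a vessel gene went both ways as well. Flt1 (27 and 0 reads) met the rule as lower, and Vwf (9 and 24) and Tek (3 and 10) as higher. From circRNAs with reads in both libraries alone, Vwf (7 and 13 reads) did not meet it. The extracellular matrix list had 75 and 34 reads (0.650, 0.420 to 0.987), the proliferation list 57 and 19 (0.478, 0.268 to 0.815) and the blood and lymphoid list 26 and 16 (0.882, 0.442 to 1.71), with 0 circRNAs past the rule. With 1 circRNA of Ebf1 left out, the blood and lymphoid list had 15 and 14 reads (1.34, 0.598 to 2.97), so its direction is not settled. Ganglion neuron and Schwann cell genes had 5 and 19 reads (5.45-fold, 1.97 to 18.7) from 4 listed circRNAs, of which 0 had enough reads to be tested. The skeletal muscle list had 0 circRNAs.

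**Figure D2:**
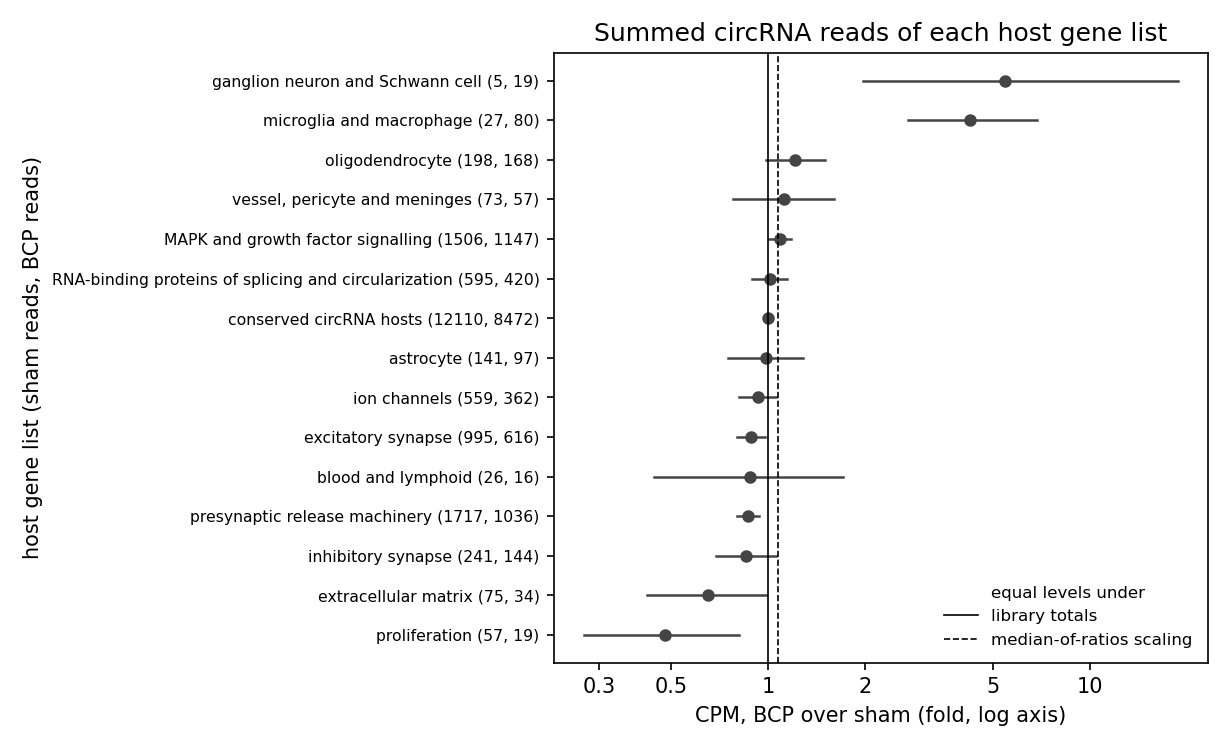
Ratio of summed circRNA CPM, BCP over sham, on a log axis for each host gene list with reads (sham and BCP reads in brackets); points are the ratio of the single libraries and lines its 95% interval from counting. The microglia and macrophage list (4.25-fold) and the ganglion neuron and Schwann cell list (5.45-fold) lie farthest to the BCP side, and the dashed line marks equal levels under median-of-ratios scaling.

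Summing the reads of all circRNAs of a gene asked whether host genes as a whole differed. Of 2144 host genes with at least 10 reads, 189 were higher and 182 lower in BCP by the same rule. The genes named here were chosen after their values were seen, from those with at least 3 circRNAs and reads in both libraries, where 73 were higher and 87 lower. Arhgap10, a GTPase activator gene with 15 circRNAs, had 67 and 125 reads (2.67-fold higher in BCP, 1.97 to 3.66). Mlip had 34 and 79 reads (3.33-fold, 2.20 to 5.14), Eif4g3 had 49 and 84 (2.46-fold, 1.71 to 3.57) and the transcription factor gene Mef2a had 69 and 99 (2.06-fold, 1.498 to 2.84). On the other side, Cdh7 had 188 and 53 reads (2.47-fold lower, 1.82 to 3.42), the cohesin gene Stag1 with 18 circRNAs had 134 and 45 (2.08-fold lower, 1.47 to 2.98), and Grm8 had 137 and 42 (2.28-fold lower, 1.60 to 3.30). Mboat2 (127 and 29 reads, 3.05-fold lower, 2.03 to 4.74) and Nop58 (83 and 8 reads, 7.24-fold lower, 3.51 to 17.3) were lower too. Each of the last 2 genes also hosts a circRNA listed at 0 in BCP that held 61 of its sham reads, and a circRNA listed at 0 in sham held 46 of the BCP reads of Eif4g3. Among the genes with most circRNAs, Rims2 had 879 and 548 reads (ratio 0.894, 0.802 to 0.996), Stk39 829 and 581 (1.00, 0.902 to 1.12), Atrnl1 583 and 298 (0.733, 0.635 to 0.844) and Ttll5 205 and 111 (0.776, 0.611 to 0.983), none past the rule. Nupr1 had 121 and 37 reads (2.28-fold lower, 1.57 to 3.39). When only circRNAs with reads in both libraries were summed, 88 host genes were higher and 29 lower. Of the genes above, Arhgap10, Mlip and Cdh7 then still met the rule on the same side, Mef2a (69 and 96 reads) and Grm8 (120 and 42) fell just short of 2-fold, and Stag1 (65 and 39), Mboat2 (48 and 29) and Nop58 (15 and 8) did not meet it. The direction turned for Eif4g3 (44 and 27 reads, ratio 0.880, 0.524 to 1.45), which did not meet the rule, and for Nupr1 (18 and 26 reads), which met it on the opposite side.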

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

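The settings that restrict circRNAs to those with reads in both libraries or with 1 host name, and 1 read in place of each 0, were chosen after the data were seen; the others were fixed beforehand. Of 92 values recomputed for the comparisons, 79 stayed within the tolerance for their kind and 13 moved. The tolerance was 1.5 times the reported value for counts and a fixed margin in percentage points for the percentage of called circRNAs that were higher. For list medians it was a bootstrap interval over the circRNAs of the list, and for folds and shares the counting interval. The counts of circRNAs with 2 reads or more could not move, since each count is 0 or at least 2. Without a read minimum, 690 circRNAs were higher and 558 lower in BCP, and with a minimum of 20 reads 139 and 112, as more or fewer circRNAs were tested. Among circRNAs with reads in both libraries 83 were lower, and 69.6% of those past the rule were higher in BCP against 51.6% of all that passed it, since most of the circRNAs that were lower were listed at 0 in BCP. That percentage was 43.2% with median-of-ratios and 42.5% with TMM scaling. Host gene sums gave 116 higher and 105 lower with a minimum of 20 reads, and 88 and 29 from circRNAs with reads in both libraries. Counted by circRNAs listed in place of reads, those without a single host made up 13.4% in sham, and spans of at most 500 bp made up 5.52% in sham and 6.45% in BCP; the cause was not tested. Of 112 circRNAs picked by the rule for names or added after the data were seen, 108 were unchanged with median-of-ratios scaling and 111 with a pseudocount of 1 read. These counts take in circRNAs with too few reads to be tested, which have no side of the size rule. They also take in those picked for the largest ratios, which had little room to change. With median-of-ratios scaling, 4 circRNAs, those of Erc1, Nalcn and Hnrnph1 among them, no longer counted as higher. With a pseudocount of 1 read, a circRNA of Ppp1cb no longer counted as lower. A DESeq2 test, leaving out replicates and a replicate block were not run. No paired analysis was possible because each group has 1 library. The rule missed many simulated changes: 29.9% of 2-fold, 65.5% of 3-fold and 86.5% of 5-fold changes were called. A 2-fold change lies at the rule's own cut, so the first share does not measure the effect of depth alone.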

Other observations

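The tests below were chosen after the result was seen, except the match on reads and the summed reads of genes with abundant mRNA, both for short-span circRNAs. Pairs of circRNAs from the same host gene are a first set of values that the comparisons leave out. Among circRNAs with at least 50 reads and reads in both libraries (203 circRNAs of 78 genes), log2 ratios within a gene had an intraclass correlation of 0.277, and shuffled hosts gave -0.165 to 0.160 in the middle 95% of 1000 shuffles. With at least 20 reads (733 circRNAs of 267 genes) it was 0.0184, and shuffled hosts gave -0.0719 to 0.0772. After the deeper set was thinned to 40% of its reads, the median correlation was 0.178 (middle 95% of 100 thinnings 0.0547 to 0.296). Neighbouring circRNAs on chromosome 1 were low in BCP: from 115000001 to 120000000 (rn6), 8 tested circRNAs summed to 270 reads in sham (124 from a single circRNA listed at 0 in BCP) and 37 in BCP with a median log2 ratio of -2.06, and from 120000001 to 125000000, 11 summed to 215 and 82 with a median of -0.85. The lowest median, -2.17, was on chromosome 17 (15000001 to 20000000; 6 circRNAs, 195 and 94 reads). No window among 254 passed the permutation scan (10000 permutations) after adjustment.

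Many circRNAs with high counts in a library were listed at 0 in the other: of 1115 with at least 20 reads in a library, 47 were at 0 in BCP and 31 in sham, such as LOC100362999 (287 reads in sham) and Brap (52 reads in BCP). These 78 argue against chance in counting independent reads, which gives 0.0512 at equal levels. Chance among reads that are not independent molecules was not tested. A shifted back-splice is argued against because 1 of the 78 had a neighbour with reads in the other library within 10 bp at both ends. A change of the whole host gene is argued against by 41 of these circRNAs, those whose host gene had enough reads in its other circRNAs. The median shift of those other circRNAs in the same direction was 0.081 on the log2 scale. Its bootstrap interval over the 41 circRNAs was -0.13 to 0.27, under the 1 that was set as needed. A host with several such circRNAs, such as Rere, entered more than once, which the interval does not take in. Where at least 50 reads on the sham scale were in a library, 21 circRNAs were at 0 in the other, 7 lay between 0 and 25% of that level and 31 between 25% and 50%, so removal of whole circRNAs by calling or filtering may account for part of the zeros. Switching of single circRNAs between BCP and sham, apart from their host genes, stays open and was not tested.

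Short-span circRNAs (at most 500 bp) were higher in BCP: 209 tested circRNAs had a median log2 ratio of 0.27, and the summed reads of all listed circRNAs of such span were 1.15-fold higher (1.10 to 1.19). Zeros are argued against as the whole cause by circRNAs with reads in both libraries. Among these, the short-span median was 0.24 above that of longer ones (bootstrap interval over circRNAs 0.05 to 0.33). A different read level is argued against too, since the median of 0.27 lay at percentile 99.97 of random lists matched on reads. Recovery by length that differed between libraries cannot be told apart from a difference between the animals: Spearman's rho of log2 ratio with genomic span was -0.0675 across 3293 circRNAs above 500 bp, which are not independent replicates, and span is not RNA length. More linear mRNA left in the BCP library likewise cannot be told apart, because circRNAs of 14 genes with abundant mRNA in spinal cord, such as Kif5a and Syt11, had 214 and 168 reads (1.13-fold, 0.914 to 1.38), too few to decide. With 1 library per group, a difference between the groups stays open for this pattern and the zeros alike.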
